A study of Homo sapiens with 6 samples.

How the data were processed

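RNA of OV2008 cells was measured on 6 arrays, 3 from cells given a negative control microRNA and 3 from cells given a miR-328-3p mimic, 3 days after transfection. Per the labels' protocols, 100 ng of total RNA was amplified into biotin-labelled sense-strand DNA by the array maker's protocol. The deposited table holds 1 value per probe set and array, on what is taken here as a log2 scale. That base is inferred: values run from 1.62 to 19.9 with medians near 4.2 on every array, which is too narrow for linear signal. Some values exceed 16, the log2 of the largest value a 16-bit scanner gives, so the values are not plain log2 scanner intensities and folds hold on this scale only. MAS5 is the only tool named in the submitters' processing notes, without a role or version, and it normally gives linear signal. The summarization, the background step and the genome build are not given in the sources used here. The values do not share 1 distribution across arrays. Arrays have no read depth, and their number, 3 per group, limits the precision.

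Groups were taken from the sample titles and source names. The description of the 3 mimic samples names the control microRNA, against their titles and source names, which were followed. Nothing in the labels says whether samples were separate cultures.

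Of 70523 probe sets, 2995 control probe sets were left out of the comparison, which leaves 67528 transcript clusters. The 25% with the lowest mean over the 6 arrays was then left out, and 50646 were tested. Gene symbols came from the platform annotation. Of the transcript clusters, 23781 carry 1 symbol, 1543 carry several and 42204 are unnamed here. Of the single symbols, 23471 matched a RefSeq gene table of assembly GRCh38.p14, through which 0 symbols needed an update. No gene was named from a probe set with several symbols, and no coordinates are given because the build of the table is not known. Where a gene had several probe sets, as 381 tested genes did, the one with the highest mean stood for it, which gave 18836 distinct genes. Of the tested probe sets, 1234 lie on alternative haplotypes.

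The deposited normalization was kept, and no pseudocount was needed. The groups were compared with limma 3.58.1 in R 4.3.3, by a linear model per probe set with empirical Bayes moderation along a mean-variance trend. The test was two-sided, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. Every adjusted p of a gene is from this test unless another is named. An exact permutation test of 3 arrays against 3 could not go below a p of 0.1 and was not used. The 30 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists, and again with an estimated correlation and with fry. Camera compares a list with all other genes, whereas fry asks whether the genes of a list move, on balance, in 1 direction, without such a comparison. A total of 39 genes are in more than 1 list. Percentiles compare a list's median with 10000 random lists of the same size matched on mean signal. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

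The groups, the test, the gene lists and the rule for named genes were fixed before the data were examined. The rule takes the 12 genes with the largest rise and the 12 with the largest fall that passed and whose groups did not overlap, passing over uncharacterised loci, olfactory receptors and the small RNA families MIR, SNORD, SNORA, RNU and RNY among others, but not SCARNA, by the start of their symbols. It adds every measured gene of the reported miR-328 targets, and up to 2 highest and 2 lowest members of each list that passed, or, where none passed, the 2 with the smallest p. Of the genes with the largest falls, 1 is not reported here. Other genes named were chosen after their values were seen, except the MIR328 precursor and its host gene, which are in the list of the microRNA pathway and do not check the label. In the report these others are EGLN3, VEGFA, PFKP, PGAM1, UQCRC2, DDIT3, ATF4, PSAT1, MTHFD2, ASNS, HSPA5, PDIA6, CALR, FTL, NQO1, GCLC and BRCA1, and in the closing section they are all the genes it names that the report does not. Some list members carry several symbols or low signal and were not analysed here.

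The fit was tested on simulated data for this comparison, with 50 genes changed at each size among 50646 probe sets. It recovered 84% of genes at a log2 change of -1, 26% at -0.5, 28% at 0.5 and 92% at 1. A total of 10 unchanged probe sets were called, and 2 of 100 unchanged lists had an unadjusted p under 0.05. In the data 5785 probe sets changed, far more than were simulated, so these shares need not hold for this comparison. The simulated values were drawn independently, without correlation between genes. The count of lists therefore does not check camera at the higher correlations estimated in the data, such as 0.18 for oxidative phosphorylation. The estimate of -0.018 for G1/S genes lies nearer to the simulated case. Alternatives were quantile normalization, centring on the array median, no filter, a filter on the lower 50%, moderation without a trend, robust moderation, the replicate number as a block, each array left out, the mean of a gene's probe sets, fitted and adjusted over genes, and, chosen after the data were seen, the removal of probe sets on alternative haplotypes and the adjustment over distinct genes alone. A test of miR-328 seed matches in 3' UTRs was planned and not run, because no genome or transcript sequence was used here.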

Results

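Whole-transcript arrays were used to measure RNA in OV2008 cells 3 days after transfection with a mimic of the microRNA miR-328-3p or with a negative control microRNA. OV2008 is an established human cell line labelled as ovarian cancer, which has been reported elsewhere to derive from a cervical carcinoma line. A microRNA mimic is a small double-stranded RNA that loads into Argonaute and represses mRNAs that pair with its seed. Each group held 3 arrays, each made from 100 ng of total RNA, and the table gave 1 log2-scale value for each of 70523 probe sets on each array. Array medians lay at 4.16, 4.19 and 4.17 in the control group and at 4.23, 4.22 and 4.19 in the mimic group. Correlations across probe sets ran from 0.9954 to 0.9969 within groups and from 0.9921 to 0.9941 between groups, and the first principal component, with 45.8% of the variance, separated the groups. Nothing in the labels says that the samples were separate cultures, so the p-values measure only the spread between these samples, which may be technical. With 2 groups and no untransfected cells analysed here, a change made by the mimic cannot be separated from one made by the control microRNA.

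The comparison of mimic with control asked which transcripts responded to miR-328-3p. In the mimic arrays CHAC1, AKR1C2, GDF15 and BNIP3 rose, as did 21 of 33 glycolysis and hypoxia genes, 17 of 35 ATF4 and unfolded protein response targets and 13 of 32 NRF2 and antioxidant genes. SYNPO2, SELENOW and DDB2 fell, as did 21 of 38 oxidative phosphorylation genes, 17 of 37 double strand break repair genes and 9 of 35 ribosomal protein genes. DDB2, the damage-binding subunit of the UV-damaged DNA recognition complex, went from 12.30 ± 0.0121 (SD, n = 3) in the control arrays to 10.79 ± 0.0545 (SD, n = 3) in the mimic arrays. That is 2.84-fold lower on this scale, with a limma adjusted p of 4.56e-05, and all 3 mimic arrays lay below all 3 control arrays.

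Of 18836 distinct genes tested, 3392 (18.0%) passed an adjusted p of 0.05, of which 1358 rose and 2034 fell. Most changes were small: 64 genes rose and 60 fell at least 2-fold. Among 14878 protein-coding genes, 1212 rose and 1903 fell. The 2 groups did not overlap for 7828 genes, which is 41.6% against the 10% that chance gives for 3 arrays against 3. Over all 50646 probe sets tested, 2413 rose and 3372 fell. When each array was centred on its own median, 30.4% of the changed genes rose in place of 40.0%, and 31.4% of the changed probe sets in place of 41.7%. With quantile normalization these shares were 41.4% and 42.3%. Leaving out any 1 array, which leaves 1 fewer sample, lowered the number of changed genes, to between 2102 and 2703. Without control array 3 there were 2192 changed genes and 3586 changed probe sets. Without mimic array 2 these numbers were 2102 and 3452, and without mimic array 1 the changed probe sets numbered 3796.

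**Figure D1:**
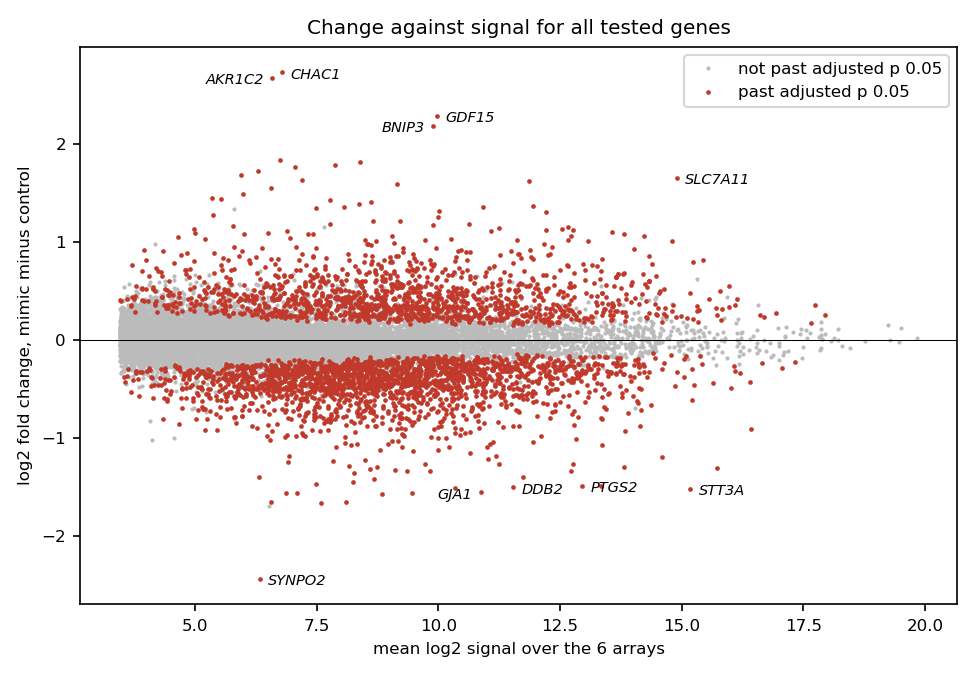
The log2 fold change (mimic minus control, vertical axis) is plotted against the mean log2 signal over the 6 arrays (horizontal axis) for all 18836 tested genes, 1 point per gene. Red points mark the 3392 genes past an adjusted p of 0.05, and the named genes include CHAC1 at 2.74 and SYNPO2 at -2.44.

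The gene with the largest rise among those named by the rule fixed for this purpose was CHAC1, a glutathione-degrading enzyme induced by ATF4, which was 6.66-fold higher in the mimic arrays (log2 fold change 2.74 ± 0.15 SE, adjusted p = 0.000232). The aldo-keto reductase AKR1C2 was 6.4-fold higher (2.68 ± 0.0988 SE, adjusted p = 7.51e-05). Its near-identical neighbour AKR1C1 was 3.4-fold higher, and since probes can be shared between the pair, the values of both are uncertain. GDF15, a stress-induced secreted factor, was 4.9-fold higher (2.29 ± 0.0633 SE, adjusted p = 4.56e-05). BNIP3, a mitophagy receptor induced by hypoxia, was 4.55-fold higher (2.19 ± 0.0418 SE, adjusted p = 4.03e-05). The value of its pseudogene BNIP3P1, at a log2 fold change of 1.84, may include BNIP3 transcripts and is uncertain. The other genes with the largest rises were NDRG1 at 1.82, the secreted glycoprotein STC2 at 1.79, the pseudogene NMRAL2P at 1.72, the cystine transporter SLC7A11 at 1.65, the transcription factor KLF7 at 1.64 and the EGFR inhibitor ERRFI1 at 1.62.

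The largest fall was that of SYNPO2, an actin-binding protein, which was 5.43-fold lower in the mimic arrays (log2 fold change -2.44 ± 0.0641 SE, adjusted p = 4.56e-05). The selenoprotein SELENOW was 3.18-fold lower (-1.67 ± 0.101 SE, adjusted p = 0.000307). The complement regulator CFI was 3.14-fold lower. MPPED2 and the receptor phosphatase PTPRZ1 both fell by 1.57 on the log2 scale, and the gap junction protein GJA1 by 1.56. STT3A, a catalytic subunit of the oligosaccharyltransferase, fell from 15.94 to 14.42 and was 2.87-fold lower. SUMF2 was 2.86-fold lower, and PTGS2, the inducible cyclooxygenase, was 2.81-fold lower (-1.49 ± 0.0615 SE, adjusted p = 9.69e-05). The small Cajal body RNA SCARNA3 also passed, at -1.57 ± 0.345 SE and an adjusted p of 0.0333. Its adjusted p rose to 0.0574 without control array 1, 0.11 without control array 3, 0.085 without mimic array 1, 0.111 without mimic array 2 and 0.07 without mimic array 3.

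**Figure D2:**
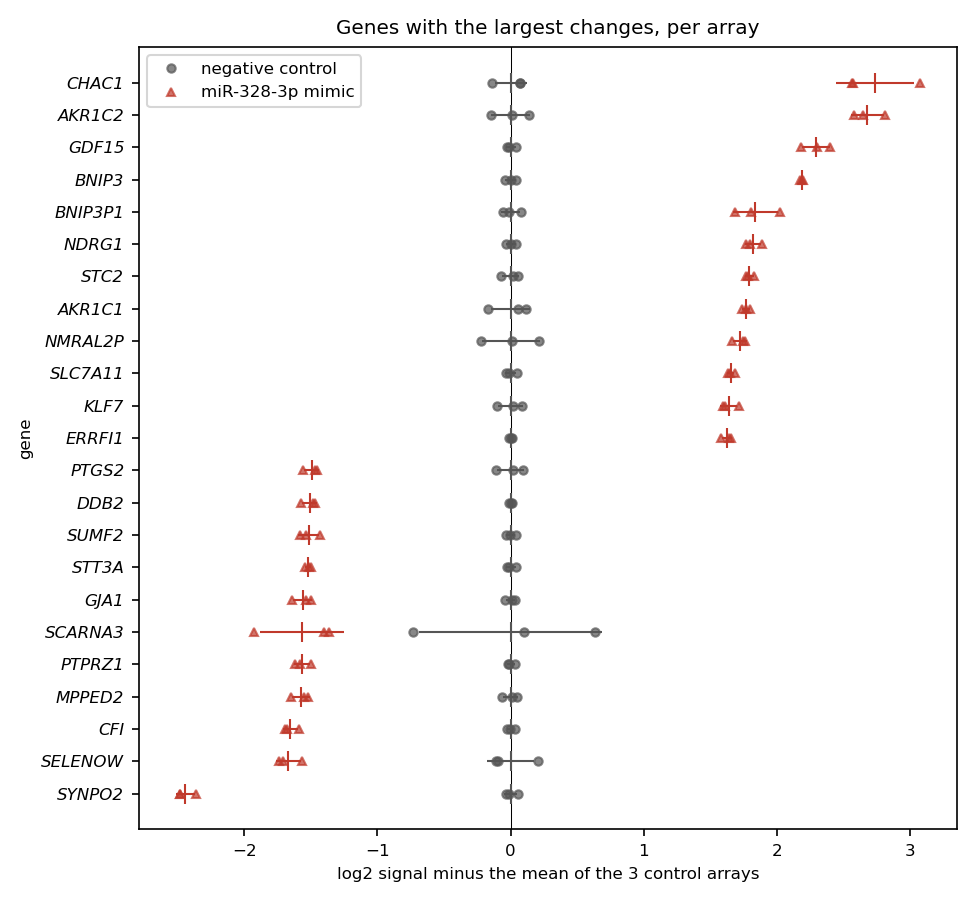
For the genes with the largest rises and falls named above, and DDB2, the log2 signal of each array minus the mean of the 3 control arrays is shown on the horizontal axis, with 1 gene per line. Grey circles are control arrays, red triangles are mimic arrays, and bars give the mean ± SD of each group. CHAC1 lies highest at 2.74 and SYNPO2 lowest at -2.44, and the groups do not overlap in any line.

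Genes reported as miR-328 targets gave a mixed picture. Of 13 measured members of this list, 5 fell, 1 rose and 7 did not pass, and the counts were the same when adjusted over the list alone. Besides DDB2, the falls were those of the phospholipase PLCE1 (-1.37 ± 0.0627 SE, 2.58-fold lower, adjusted p = 0.000135), the membrane metalloproteinase MMP16 (-0.76 ± 0.0596 SE, 1.69-fold lower, adjusted p = 0.00075), the glucose transporter SLC2A1 (-0.21, adjusted p = 0.0369) and the hyaluronan receptor CD44 (-0.18, adjusted p = 0.0247). SLC2A1 no longer passed whichever array was left out, with adjusted p of 0.071, 0.105 and 0.107 without control arrays 1, 2 and 3 and of 0.0643, 0.134 and 0.097 without mimic arrays 1, 2 and 3. CD44 passed only on its brighter probe set, the other standing at -0.09, and its adjusted p was 0.0545 and 0.0916 without control arrays 1 and 3 and 0.0773, 0.102 and 0.0689 without mimic arrays 1, 2 and 3. The drug efflux pump ABCG2 rose, from 5.33 ± 0.0738 to 5.86 ± 0.0539 (SD, n = 3; adjusted p = 0.00501). Values that did not pass were -0.09 for BACE1, -0.06 for IGF1R, -0.02 for CACNB1, 0.04 for PIM1, 0.07 for CACNA1C, 0.09 for H2AX and 0.11 for SFRP1. In the control arrays CACNA1C at 3.60 and SFRP1 at 3.96 lay below the array medians of 4.16 to 4.19, so a fall could hardly show. Signal was also low for CACNB1 (4.96), PIM1 (5.13) and BACE1 (5.85), and higher for IGF1R (8.45) and H2AX (10.06). The list as a whole did not pass against other genes (camera adjusted p = 0.111). DDB2 was put in the list from knowledge of this study, so its fall is not independent evidence of the list's direction. The MIR328 precursor, whose probe set does not measure a transfected mature mimic, stood at 0.18 and its host gene ELMO3 at -0.11, neither of which passed.

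Glycolysis and hypoxia genes rose together. Of 33 measured, 21 rose, 3 fell and 9 did not pass, or 23 rose and 3 fell when adjusted over the list alone, and the median log2 fold change was 0.47 (camera adjusted p = 5.06e-12, or adjusted p = 0.246 with an estimated correlation). Members included BNIP3 and NDRG1 as above, the prolyl hydroxylase EGLN3 at 1.27, the angiogenic factor VEGFA at 1.09, and the glycolytic enzymes PFKP at 0.72, PGAM1 at 0.68 and PGK1 at 0.66. The 3 that fell were ADM (-0.63), SLC2A1 (-0.21) and PFKM (-0.26). PFKM had adjusted p of 0.056 and 0.0574 without control array 3 and mimic array 2, and SLC2A1 was lost whichever array was left out, with adjusted p from 0.0643 without mimic array 1 to 0.134 without mimic array 2. Oxidative phosphorylation genes went the other way. Of 38 measured, none rose, 21 fell and 17 did not pass, or 28 fell when adjusted over the list alone, with a median of -0.26 (camera adjusted p = 3.1e-11, or adjusted p = 0.246 with an estimated correlation). COX6A1, a subunit of cytochrome c oxidase, fell by 1.31, the complex I subunit NDUFA8 by 0.72 and the complex III core subunit UQCRC2 by 0.47.

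Targets of ATF4 and of the unfolded protein response shifted upwards. Of 35 measured, 17 rose, 2 fell and 16 did not pass, or 20 rose and 3 fell when adjusted over the list alone, with a median of 0.27 (camera adjusted p = 1.03e-07, or adjusted p = 0.246 with an estimated correlation). The members that rose included CHAC1 and STC2, the transcription factors DDIT3 at 1.35 and ATF4 at 0.72, and the serine, folate and asparagine enzymes PSAT1 at 1.10, MTHFD2 at 0.98 and ASNS at 0.82. The endoplasmic reticulum chaperones HSPA5 at 0.02, PDIA6 at -0.07 and CALR at -0.09 did not pass, and PDIA4 fell by 0.41. The mitochondrial enzyme SHMT2 fell by 0.50. Among 32 NRF2 and antioxidant genes, 13 rose, 6 fell and 13 did not pass, or 17 rose and 9 fell when adjusted over the list alone, with a median of 0.17 (camera adjusted p = 0.00448, or adjusted p = 0.251 with an estimated correlation). AKR1C2, AKR1C1 and SLC7A11 rose most, and the ferritin subunit FTL rose by 1.01. NFE2L2, which encodes NRF2 itself, fell by 0.42, its target NQO1 by 0.19, the glutathione synthesis subunit GCLC by 0.35 and the pentose phosphate enzyme PGD by 0.64.

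Cholesterol synthesis genes shifted upwards, with 7 rising, 2 falling and 11 not passing of 20 measured, or 9 rising and 2 falling when adjusted over the list alone (median 0.16, camera adjusted p = 0.000575, or adjusted p = 0.246 with an estimated correlation). INSIG1, a sterol-regulated retention protein, rose by 1.22 and the sterol demethylation enzyme MSMO1 by 1.11, while TM7SF2 fell by 0.57. ACAT2 passed at -0.16 but was lost whichever array was left out, with adjusted p of 0.0789, 0.119 and 0.119 without control arrays 1, 2 and 3 and of 0.104, 0.123 and 0.118 without mimic arrays 1, 2 and 3.

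Genes of double strand break repair and of the G1/S phase shifted downwards. Of 37 double strand break repair genes, none rose, 17 fell and 20 did not pass, or 1 rose and 22 fell when adjusted over the list alone, with a median of -0.21 (camera adjusted p = 4.24e-07, or adjusted p = 0.246 with an estimated correlation). The nuclease MRE11 fell by 0.57, the exonuclease EXO1 by 0.55 and BRCA1, named here after its value was seen, by 0.54. Of 35 G1/S genes, 3 rose, 14 fell and 18 did not pass, or 6 rose and 20 fell when adjusted over the list alone, with a median of -0.17 (camera adjusted p = 0.0073, or adjusted p = 0.246 with an estimated correlation). CDCA7 fell by 1.09 and the replicative helicase factor GINS2 by 0.59, whereas cyclin E2, CCNE2, rose by 1.03 and the ribonucleotide reductase subunit RRM2 by 0.84. Nucleotide excision repair, the pathway of DDB2, had 5 genes that rose, 8 that fell and 23 that did not pass of 36, or 5 and 10 when adjusted over the list alone (camera adjusted p = 0.233). GTF2H5, a subunit of TFIIH, fell by 0.77, and RAD23B rose by 0.35. ERCC1 also passed at 0.35, with adjusted p of 0.0501 without control array 3 and 0.0504 without mimic array 2.

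Of 35 cytosolic ribosomal protein genes, 1 rose, 9 fell and 25 did not pass, with the same counts when adjusted over the list alone and a median of -0.12 (camera adjusted p = 6.16e-06, or adjusted p = 0.251 with an estimated correlation). RPL11 fell by 0.67 and RPL8 by 0.61. RPL28 passed at 0.19 but was lost whichever array was left out, with adjusted p from 0.103 without control array 1 to 0.151 without mimic array 2, and when each array was centred on its median (adjusted p = 0.127). Among 11 constitutive reference genes, often used to scale measurements, 5 rose, 1 fell and 5 did not pass, or 6 rose and 2 fell when adjusted over the list alone (median 0.14, camera adjusted p = 0.0359, or adjusted p = 0.25 with an estimated correlation). The glycolytic enzyme PGK1 rose by 0.66 and the RNA polymerase II subunit POLR2A by 0.52, and YWHAZ fell by 0.73. The shift of this list no longer passed without control array 2 (adjusted p = 0.0508), control array 3 (0.0543) or mimic array 2 (0.0563).

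**Figure D3:**
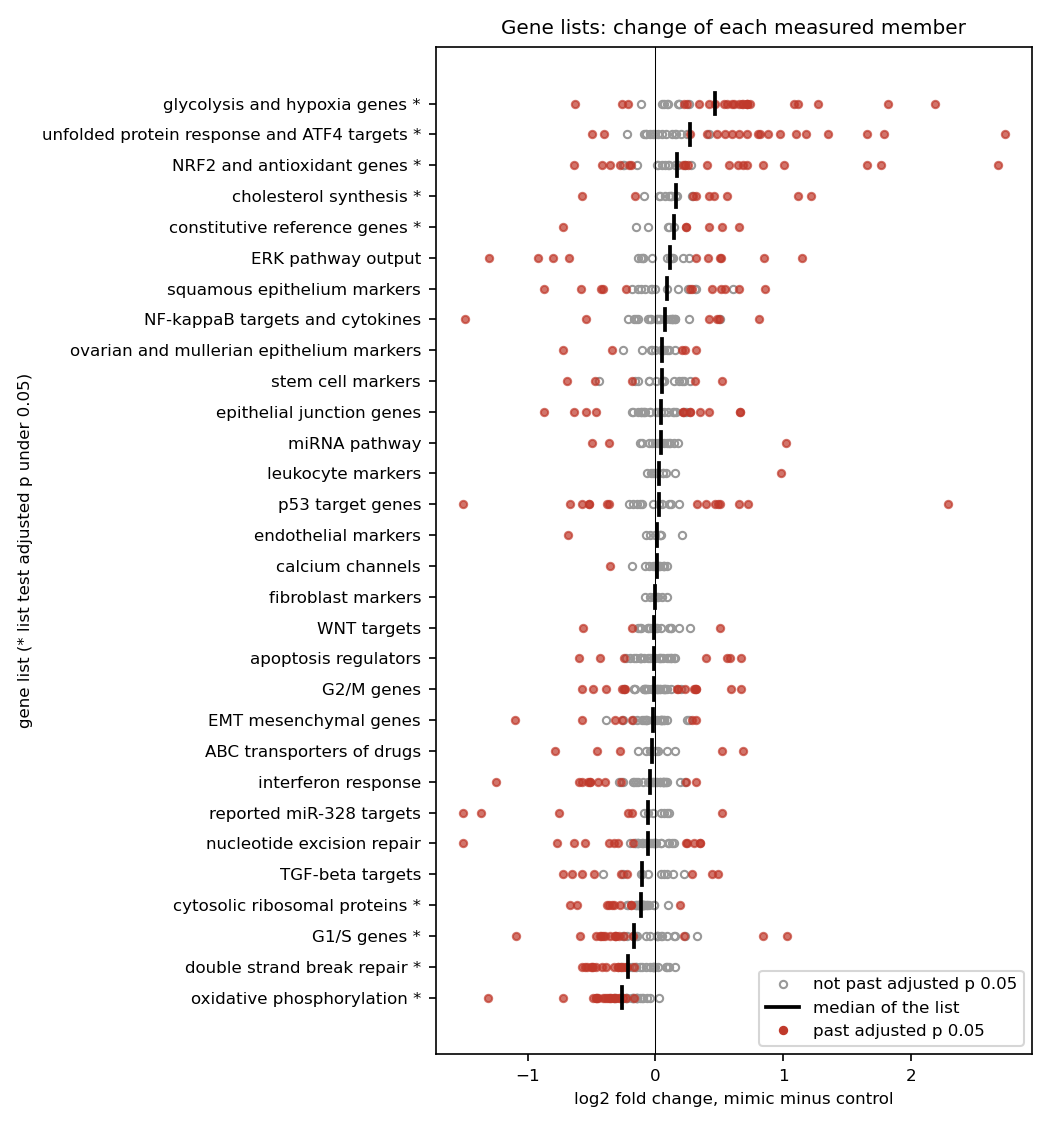
Each line is 1 of the 30 gene lists, and each circle is a measured member at its log2 fold change (mimic minus control, horizontal axis), filled where it passed an adjusted p of 0.05. Black bars mark the list medians, which run from -0.26 for oxidative phosphorylation to 0.47 for glycolysis and hypoxia genes, and asterisks mark the 9 lists past an adjusted p of 0.05 in the list test with the preset correlation, of which 0 passed with an estimated correlation.

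The remaining lists did not pass the list test, although single members changed in both directions in all but the calcium channel, fibroblast, leukocyte and endothelial lists. Of 27 p53 target genes, 8 rose, 7 fell and 12 did not pass, or 9 rose and 10 fell when adjusted over the list alone (camera adjusted p = 0.959). GDF15 and CDKN1A, the cell cycle inhibitor, rose by 2.29 and 0.72, and DDB2 and CYFIP2 fell by 1.51 and 0.67. Of 44 G2/M genes, 9 rose, 6 fell and 29 did not pass, or 10 rose and 8 fell when adjusted over the list alone (camera adjusted p = 0.891). The mitotic kinase PLK1 rose by 0.67 and the phosphatase CDC25B by 0.59, and the kinesin KIF20A fell by 0.58 and CDCA8 by 0.49. Apoptosis regulators included 4 genes that rose, 3 that fell and 23 that did not pass, or 4 and 4 when adjusted over the list alone (camera adjusted p = 0.959), with PMAIP1 at 0.67, FADD at 0.59, CASP6 at -0.60 and BIRC2 at -0.43. Of 19 stem cell markers, 2 rose, 3 fell and 14 did not pass, or 5 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.891), with ALDH1A3 at -0.69, SOX2 at -0.47 and the integrin ITGA6 at 0.31.

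Signalling outputs were likewise mixed. Of 21 ERK pathway output genes, 6 rose, 4 fell and 11 did not pass, or 8 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.46). The immediate early gene FOS fell by 1.30 and the feedback inhibitor SPRY1 by 0.92, while IER3 rose by 1.14 and ETV5 by 0.85. Of 27 NF-kappaB targets and cytokines, 4 rose, 2 fell and 21 did not pass, or 5 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.336), with the interleukins IL1A at 0.81 and IL1B at -0.54 on opposite sides, and TNFAIP3 at 0.50. Of 19 TGF-beta targets, 3 rose, 6 fell and 10 did not pass, or 4 rose and 8 fell when adjusted over the list alone (camera adjusted p = 0.32), with ID3 at -0.72, BMP4 at -0.65 and TGFB1 at 0.49. CDKN2B passed at 0.44 but was lost whichever array was left out, with adjusted p from 0.0514 without control array 2 to 0.0912 without mimic array 2. Of 18 WNT targets, 1 rose, 2 fell and 15 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.959), with CCND1 at 0.51 and LEF1 at -0.56. Of 36 interferon response genes, 2 rose, 9 fell and 25 did not pass, or 3 rose and 11 fell when adjusted over the list alone (camera adjusted p = 0.133). The immunoproteasome subunit PSMB9 fell by 1.25, and its 8 probe sets, 7 of them on alternative haplotypes, lay between -1.29 and -1.18. IFIT1 passed at -0.59, with adjusted p of 0.0899, 0.0549 and 0.101 without control arrays 1, 2 and 3 and of 0.078 and 0.079 without mimic arrays 2 and 3. SAMD9L passed at 0.32, with adjusted p of 0.0684 without control array 3 and of 0.066, 0.0637 and 0.0539 without mimic arrays 1, 2 and 3, and IFIH1 at 0.24, lost whichever array was left out, with adjusted p from 0.0533 without mimic array 1 to 0.141 without mimic array 2.

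Among 33 epithelial junction genes, 8 rose, 4 fell and 21 did not pass, or 10 rose and 5 fell when adjusted over the list alone (camera adjusted p = 0.65). E-cadherin, CDH1, and plakoglobin, JUP, each rose by 0.66, and the desmosomal genes DSG3 and PKP2 fell by 0.88 and 0.64. Of 31 mesenchymal genes of epithelial-mesenchymal transition, 2 rose, 5 fell and 24 did not pass, or 2 rose and 6 fell when adjusted over the list alone (camera adjusted p = 0.46), with the matricellular genes CCN1 at -1.10 and CCN2 at -0.58. TGFBI passed at 0.29, with adjusted p of 0.0544 and 0.0603 without control arrays 1 and 3 and of 0.0626, 0.0746 and 0.0558 without mimic arrays 1, 2 and 3, and FOSL1 at 0.32, lost whichever array was left out, with adjusted p from 0.073 without mimic array 2 to 0.122 without control array 3. Of 14 ABC transporters of drugs, 2 rose, 3 fell and 9 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.837). ABCB1, the P-glycoprotein gene, fell by 0.78 and ABCC5 by 0.45, while ABCC2 and ABCG2 rose by 0.69 and 0.52. The microRNA pathway list had 1 gene that rose, 2 that fell and 14 that did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.837). DICER1, which cuts precursor microRNAs, rose by 1.02, and TNRC6B and PRKRA fell by 0.50 and 0.36. Of 16 calcium channel genes, none rose, 15 did not pass and CACNA2D1 fell by 0.35, with the same counts when adjusted over the list alone (camera adjusted p = 0.959). CACNA2D1 had adjusted p of 0.064, 0.0596 and 0.0558 without control arrays 1, 2 and 3 and of 0.0846 and 0.0859 without mimic arrays 1 and 2.

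Markers of cell types were included because the identity of the line and the purity of a sample bear on every value. The changes given here compare the groups and test neither. Some markers had low signal in the control arrays, such as FBN1 at 4.09 and COL1A1 at 4.30, so a fall could hardly show. Of 25 squamous epithelium markers, 7 rose, 5 fell and 13 did not pass, or 10 rose and 5 fell when adjusted over the list alone (camera adjusted p = 0.501), with SFN at 0.86, DSG3 at -0.88 and the keratin KRT15 at -0.58. SPRR3 passed at 0.66, with adjusted p of 0.0539, 0.0564 and 0.0545 without control array 1, control array 2 and mimic array 3. Of 16 ovarian and mullerian epithelium markers, 3 rose, 2 fell and 11 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.766), with MECOM at -0.72 and KRT18 at 0.32. ESR1 passed at -0.34 but had an adjusted p of 0.0539 without mimic array 1. KRT8 passed at 0.23 on 1 of its 2 probe sets, while the other stood at 0.49 and did not pass. The adjusted p of KRT8 was 0.0594, 0.0579 and 0.0828 without control arrays 1, 2 and 3 and 0.0612 and 0.0859 without mimic arrays 1 and 2. None of 9 fibroblast markers passed, in the test over all probe sets or adjusted over the list alone (camera adjusted p = 0.959), and those with the smallest p were FBN1 at -0.08 and COL1A1 at 0.09. CD68, a lysosomal protein used as a macrophage marker, rose by 0.99 as the single changed gene of 10 leukocyte markers (camera adjusted p = 0.426), and CDH5 fell by 0.68 as the single changed gene of 8 endothelial markers (camera adjusted p = 0.891), with the same counts when adjusted over the list alone.

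All values are on the deposited log2-like scale, in 3 arrays per group, and the number of arrays limits the precision. None of the 9 list shifts passed when the correlation between genes was estimated from these arrays in place of the preset value of 0.01. Of the list tests that compare with other genes, only the preset form of camera therefore called these shifts. Against random lists matched on signal, the median of oxidative phosphorylation lay at percentile 0. That of the ribosomal proteins lay at 2.42, near the bound of 2.5. Such random lists do not allow for correlation between genes, and the other lists that passed were not compared with them. The estimated correlation lay below 0.01 for G1/S genes (-0.018) and for reference genes (0.0036), so a higher correlation does not account for the loss of these lists. The estimated form also refers its statistic to the few residual degrees of freedom that 6 arrays leave, which raises p at any correlation. The loss of the 9 shifts is therefore not a measure of correlation alone. All 9 lists passed with fry, which does not compare a list with other genes.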

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

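Both results here come from control probe sets, which the comparison leaves out, and the look at them was chosen after the data were seen. Signal differing between the groups appeared in 2 of 5 classes of control probe sets. Calls were made at a limma adjusted p under 0.05, with adjustment over the 2995 control probe sets alone. Of 1465 exon and junction control probe sets, 20 were higher and 28 lower in the mimic arrays. Their median log2 fold change was -0.0046, and their median signal in the control arrays was high, at 13.49. Of 1344 numbered control probe sets, 10 were higher and 19 lower, with a median log2 fold change of -0.023. Both classes had a smaller share of calls than the 11.4% of tested transcript cluster probe sets. None of the 8 bacterial spike-in, 155 ERCC spike-in or 23 background probe sets passed in either direction.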

How the results depend on the processing

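Of 119 named genes, 110 passed with all arrays, 93 of these passed under every alternative run, and none took the opposite sign with a call. The rule names mainly genes that passed with large changes, so this does not stand for all 3392 changed genes. Of those, 2082 (without mimic array 2) to 2556 (without control array 1) passed again when 1 array was left out. In 107 results of 1 gene under 1 alternative the call was lost with the same direction; among them, quantile normalization ended those of SLC2A1, FOSL1, ACAT2 and KRT8, and median centring those of FOSL1, IFIH1 and RPL28. The removal of probe sets on alternative haplotypes and the adjustment over genes alone were chosen after seeing the data. Changed genes numbered 3320 with quantile normalization (3123 shared with the 3392), 3412 with median centring (3072 shared), 3076 without a filter, 3864 with the lower 50% left out, 2923 without the trend, 3368 with robust moderation and 3374 without alternative haplotypes. Genes changed at least 2-fold numbered from 121 to 130 over all alternatives. With the mean of all probe sets of a gene, 4998 genes changed and 2074 rose, in a fit made and adjusted over genes. Adjustment over genes alone, with the main fit kept, gave 4044 and 1629. Averaging alters the values of only the 381 genes with several tested probe sets, too few for most of the rest. The larger part of it therefore comes from refitting on genes, although the 2 shares were not separated. Leaving out 1 array, which leaves 1 fewer sample, gave 2102 (without mimic array 2) to 2703 genes (without control array 1), of which 831 to 1150 rose and 1271 to 1559 fell. Control array 3 gave 2192. Probe sets numbered 3452 to 4796, with 1403 to 2242 rising and 2049 to 2644 falling, with 3586 without control array 3 and 3796 without mimic array 1. With the replicate number as a block, 2545 genes changed, 2461 of them among the 3392. Whether the numbers pair the samples cannot be told from these arrays. Deviations of same-numbered arrays correlated at 0.14, -0.05 and 0.18 across probe sets. The values for numbers 1 and 3 were the highest between the groups, whereas neither array of number 2 correlated best with its own number. Centring lowered the share of rising genes from 40.0% to 30.4%, whereas quantile normalization gave 41.4%.

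With the correlation estimated, 0 of 30 lists passed in place of 9, at adjusted p of 0.246 (glycolysis and hypoxia, ATF4 targets, cholesterol, oxidative phosphorylation, double strand break repair, G1/S), 0.25 (reference genes) and 0.251 (NRF2, ribosomal proteins). With fry, which does not compare a list with other genes, 16 passed, the 9 and the reported targets (3.15e-05), interferon response (0.000179), TGF-beta (0.000605), nucleotide excision repair (0.000684), mesenchymal genes (0.00447), leukocyte markers (0.00961) and ABC transporters (0.0184). The constitutive reference genes ranged from 0.0288 to 0.0563 over the arrays left out, above 0.05 without control array 2 (0.0508), control array 3 (0.0543) and mimic array 2 (0.0563); the cause was not tested. The median, mean and test differ in sign for stem cell, ovarian, calcium channel, WNT, G2/M, apoptosis and endothelial lists, none of which passed. Fibroblast markers gave no value with the lower 50% left out, where under 3 members remained. Seed-match tests, all their alternatives and the pseudocounts were not run.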

Other observations

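In the observations below, the proteasome list was written after the values of all proteasome genes had been seen, and the other added lists after the main results were known. The signal-level tests on both falling lists, split into 1 per list once the value was known, and both the signal-level and the scaling test on the proteasome list were likewise written after their results were seen, while the tests on splits, ubiquitin shuttles, heat shock genes, short abundant mRNAs and mitochondrial ribosomal proteins were written before. A tolerance of 2 Monte Carlo standard errors around the bounds of the highest and lowest 2.5% was set after the percentiles had been seen. So was the choice to leave an explanation open, at least in part, where a list missed its bound but passed camera. That choice applied to the mitochondrial ribosomal proteins, which count against their explanation by the bound as first written. A loss of part of the short abundant mRNAs is left open as well, although the list of other such mRNAs did not pass camera.

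Genes of the proteasome, the protease that degrades ubiquitin-tagged proteins, rose together in the mimic arrays. Of 30 measured core and regulatory subunits, 27 rose, 1 fell and 2 did not pass, with a median log2 fold change of 0.68 (camera adjusted p = 8.77e-21 over 7 lists, or adjusted p = 0.0676 with an estimated correlation). The largest rises were those of PSMD3, from 8.36 to 9.96, PSMC4 at 1.31 and PSMD1 at 1.16. PSMC1 fell by 0.57, and PSMC3 at -0.16 and SEM1 at 0.38 did not pass. The list leaves out 3 assembly chaperones, which did not rise either: PSMD5 fell by 0.25 (adjusted p = 0.00979), and PSMD9 at -0.15 and PSMD10 at -0.09 did not pass. The immunoproteasome subunits PSMB9 and PSMB8, members of the interferon response list, which did not pass, fell by 1.25 and 0.51, and PSMB10 at -0.11 did not pass. Of the activator subunits, PSME2 fell by 0.37 and PSME1 at -0.22 did not pass. The segregase p97, VCP, rose by 0.88, its cofactors NPLOC4 by 1.26, UFD1 by 0.94 and PLAA by 1.32, and the proteasome-bound deubiquitinase USP14 by 0.91, whereas UBXN1 at -0.07 and FAF1 at -0.03, of the list of ubiquitin shuttles and p97 partners, did not pass. NFE2L1, which encodes a transcription factor of proteasome genes, rose by 0.37 (adjusted p = 0.0106). Apart from PSMB9, the genes named here outside the proteasome list were picked after their values were seen, and those in no list were not tested together.

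Some aminoacyl-tRNA synthetases rose as well, with GARS1 at 1.08, MARS1 at 0.91 and AARS1 at 0.67, whereas QARS1 and KARS1 fell by 0.50 and 0.32. These genes were picked after their values were seen and were not tested as a list. Many of the strongest changes are in probe sets unnamed here. Of 30736 tested probe sets without a single symbol, 2279 changed, 142 of them at least 2-fold. The 2 that rose most were TC01005754.hg.1, by 4.61, and TC06003702.hg.1, by 4.39, and the 2 that fell most were TC19002185.hg.1, at -2.12, and TC05000529.hg.1, at -2.08.

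The rise of the proteasome genes is not a trend with signal level, since its median lay at percentile 100 of the random lists matched on signal. Nor do differences in scale left between the deposited arrays account for it, because the median was 0.65 after quantile normalization. Array medians were close beforehand, from 4.16 to 4.23, so little change could come from that step. The submitters' own processing was not tested. As a hypothesis, cells with the mimic may respond to a lower proteasome capacity, and the ubiquitin shuttles and p97 partners, 9 of 18 rising and 2 falling, lay at percentile 99.96, although their shift was lost with an estimated correlation (camera adjusted p = 0.00042, or adjusted p = 0.0676 with an estimated correlation). They include NSFL1C at 0.98 and SQSTM1 at 0.87, while DERL2 fell by 0.84 and NBR1 by 0.22. Heat shock chaperones, 5 of 16 rising and none falling (camera adjusted p = 0.00124, or adjusted p = 0.139 with an estimated correlation), lay at percentile 97.2, which missed the highest 2.5% required as first written and lies within the tolerance set later, so a wider response to misfolded protein stays open, as does an effect of the control microRNA.

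The fall of respiratory chain and ribosomal protein genes might reflect a loss of short abundant mRNAs. Of 35 ribosomal protein genes, 9 fell, 1 rose and 25 did not pass. Both list shifts were lost with an estimated correlation (camera adjusted p = 0.246 and 0.251 over 30 lists). Other short abundant mRNAs, with 1 rising and 8 falling of 36, lay at percentile 36.08 (camera adjusted p = 0.099). Their median counts against a loss of such mRNAs as a whole, whereas a loss of part of them stays open. Transcript length was not measured here. A trend with signal level does not reach the respiratory chain genes, at percentile 0, and stays open for the ribosomal protein genes, at percentile 2.42 and within the tolerance of the bound. Mitochondrial ribosomal proteins had a median of -0.093 at percentile 4.47, inside the range of matched lists, but 20 of 73 fell, 1 rose and camera gave an adjusted p of 8.85e-06, or an adjusted p of 0.132 with an estimated correlation. By the bound as first written, this median counts against a fall of mitochondrial gene products in general. A fall of fewer members does not move a median far, so a fall of part of them stays open. What lowers the respiratory chain genes therefore stays open, the mimic and the control microRNA included.

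With 10 splits of the 6 arrays into 3 and 3, the share of splits with as many changed probe sets cannot fall under 0.05. Of these, 1 split, the real one, gave 5785 changed probe sets, and the highest of the 9 others gave 0 by limma, with 1403 to 4177 at an unadjusted p under 0.05. Each of the 9 others puts arrays of both groups on each side, so a difference between the groups adds to the spread within its sides. Few calls were likely there beforehand, and the contrast with the real split decides nothing about chance.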
